A study of Caenorhabditis elegans with 3 samples.

How the data were processed

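Whole L4 larvae of 1 transgenic C. elegans strain were analysed, in 3 libraries from 2 biological replicates. Per the labels, chromatin was sonicated to fragments of 200 to 800 bp, the fusion protein was recovered with an antibody against GFP, and the assembly was ce11. The authors deposited 4 region lists. Per the labels and the notes deposited with them, candidate regions (peaks together with background) were made from the reads of replicate 1, of replicate 2 and of both together, each against a control. Both technical libraries of replicate 1 are tied to a single alignment and were counted as 1 replicate. The control reads were not analysed here. A thresholded list was derived from the candidate lists, the combined one included, with the irreproducible discovery rate. That rate weighs how consistently regions rank between lists. The peak caller, the aligner, the rate's threshold and all versions are not given in the sources used here.

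The candidate lists held 30000 regions for replicate 1, 23415 for replicate 2 and 28443 for both together. All 635 thresholded regions were found with identical limits and signal in the combined list. Each deposited region carries a signal value, a score set by the authors' peak caller with no stated unit, which was used only to rank and describe regions within a list. The deposited lists also give a −log10 q per region, which was 1.97 for every thresholded peak and so ranked nothing. The summit was taken from the offset that the authors deposited for each region. No error rate that differed between thresholded peaks was given. The stricter setting planned before the data were examined was therefore the stronger part of the list by signal value. Regions whose true height depends on read depth cannot be corrected for it, since no read counts were used, and a site missing from the list was not detectable at an unknown depth rather than absent. Mappability and DNA copy number also enter such scores, as does the choice of control.

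Chromosome lengths of ce11 matched those of the reference assembly WBcel235, and no region ran past a chromosome end. Genes, biotypes and 5' ends came from Ensembl release 115. The annotation gave no symbol for 2811 genes, and 2773 of these were named through their WormBase identifier in the RefSeq annotation of the same assembly, which also gave tRNA isotypes and products. Mitochondrial peaks were left out of the comparisons, which used the 620 nuclear peaks and a nuclear genome of 100272607 bp. A summit counted as promoter from 1000 bp upstream to 200 bp downstream of the 5' end of any gene except pseudogenes and piRNA genes, and as near a non-coding gene within 200 bp of its body. A peak near several kinds of non-coding gene was put in the tRNA, snoRNA, snRNA or other class in that order.

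Shares were tested with two-sided exact binomial tests against the genome share, and have 95% Clopper-Pearson intervals. Gene lists, biotypes and words were tested with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment within each family, at a threshold of 0.05. The lists covered gene families, housekeeping complexes and markers of 6 tissues. Of these, 38 had at least 5 annotated members, and 1 list did not and was not tested. Replicate lists were compared with 1000 random circular shifts, and signal medians with a permutation test of 100000 resamples. Peaks and genes are the units of these tests, so their p-values do not measure the spread between worms. With 2 biological replicates and no second group, no test across replicates was run. Intervals and limits for a count of 0 cover counting error only, the limit being 3 counts of the total.

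Groups, tests, gene lists, the other settings to try and the rule for named genes were fixed before the data were examined. The rule took 25 protein-coding genes, each with the nearest 5' end within 1000 bp of one of the strongest nuclear summits, the tagged gene and unc-119, and up to 4 bound members with the highest signal of each list or biotype past the threshold, with none of a depleted list. Genes whose symbol is shared by several records (an ncRNA gene and an snRNA gene), and ncRNA genes under a snoRNA peak, were not named. The other settings fixed in advance were the stronger peaks only, other promoter windows, other distances and overlap rules, other backgrounds, longer words, masked repeats, and each replicate left out in turn. For the last, the 620 strongest nuclear candidates of the other replicate replaced the thresholded list. Settings added after seeing the data left out peaks near tRNA genes, near tRNA, snoRNA or snRNA genes, or near any non-coding gene, left out genes near tRNA, snoRNA or snRNA genes, kept nuclear peaks only, or compared biotypes with shifted summits.

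The tests were tried on simulated data first. For promoters, 60.0% of 620 simulated summits were planted and 60.0% recovered. For gene lists, all 160 planted lists were called and 0 of 600 unplanted ones. There, bound genes were drawn independently rather than through summits, and planted at about the share found for ribosomal protein genes. Recovery of lists with lower shares, or with genes that share a peak, was not tried. For words, 1 planted word ranked at the top, and 4 others, of 2080, were also called. For promoters 6.00% and for chromosome X 7.00% of 100 unplanted sets were called at the threshold. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.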

Results

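Chromatin immunoprecipitation with sequencing was used to map where Y5F2A.4, annotated as a protein with a C2H2-type zinc finger domain, was found on the Caenorhabditis elegans genome. The strain carried an integrated transgene in which the gene was fused to GFP and FLAG tags, together with a wild-type unc-119 copy that rescues the host mutation. Whole worms of mixed sex were grown for 48 hours to the L4 larval stage after synchronisation by bleaching and L1 starvation. DNA bound to the fusion protein was recovered with an antibody against GFP. The 3 libraries form a single group, with 2 technical libraries of biological replicate 1 and 1 library of biological replicate 2, so the design holds no contrast between conditions. Read depth is unknown, because the deposited lists hold regions and scores without read counts. The question addressed was where on the genome the tagged protein was detected.

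The thresholded list held 635 reproducible peaks in assembly ce11, 620 on the nuclear chromosomes and 15 on the mitochondrial genome. Of these, 553 had the same width of 376 bp and the rest ranged from 97 to 592 bp. The authors' signal value had a median of 132 and ran from 100.5 to 4430 over the whole list, and to 718 among nuclear peaks. Both biological replicates held a candidate summit within 200 bp of 615 of the 620 nuclear peaks, or 99.2%. Replicate 2 held one for all 620. The thresholded list was selected from these candidates by consistency of rank. This presence in both, and in part the correlation across peaks, is therefore not independent evidence of agreement. Some peaks still ranked far apart, such as 1 on II, 3439233 to 3439608, at rank 7474 in replicate 1 and 238 in replicate 2. Across the 615 peaks the signal values of the replicates had a Spearman rho of 0.464 and a Pearson r of 0.575 on the log2 scale. These are correlations across peaks, and peaks are not independent replicates.

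When the 620 strongest nuclear candidate regions of each replicate were compared, 356 regions of replicate 1, or 57.4%, had a summit within 200 bp of a summit in replicate 2. Random circular shifts along the chromosomes gave a mean of 0.255% and a maximum of 1.13%. The permutation p of 0.001 is the smallest that 1000 shifts can give.

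**Figure D1:**
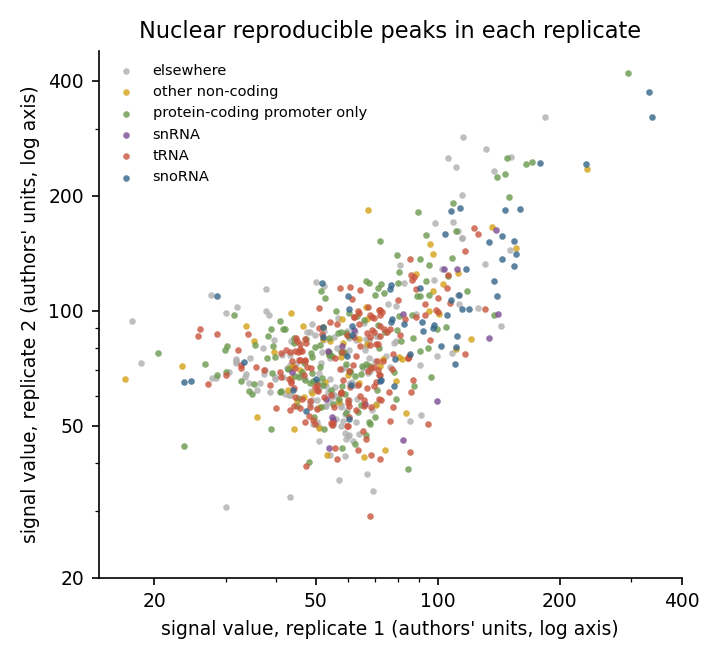
Signal value of each nuclear reproducible peak in replicate 1 (x axis) and replicate 2 (y axis), both in the authors' units on log axes, 1 point per peak, coloured by what lay near the summit. The 615 peaks with a candidate region in both replicates rise together, with a Spearman rho of 0.464 across peaks.

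Genes for small structural RNAs lay under a large part of the peaks. A tRNA gene body was within 200 bp of 181 nuclear summits, which was 29.2% of them (95% Clopper-Pearson interval 25.6 to 32.9). A snoRNA gene, encoding a guide for RNA modification, was near a further 59 (9.52%, interval 7.32 to 12.1). An snRNA gene was near 17 more (2.74%, interval 1.61 to 4.35), and another kind of non-coding gene near 57. The other candidates were the 27673 nuclear regions of the combined list that overlapped no reproducible peak. Among them the tRNA share was 0.986% and the snoRNA share 0.333%. The tRNA share was 29.6-fold and the snoRNA share 28.6-fold higher among reproducible peaks, with adjusted p of 1.96e-183 and 1.26e-57 by Fisher's exact test. A further 142 summits lay only in a protein-coding promoter (22.9%, against 20.3% of the other candidates, adjusted p = 0.107 by Fisher's exact test), and 164 lay in none of these places (26.5%, against 72.5%). Summits near non-coding genes were taken out of the promoter class first but kept in its total. That p therefore does not measure enrichment at protein-coding promoters.

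**Figure D2:**
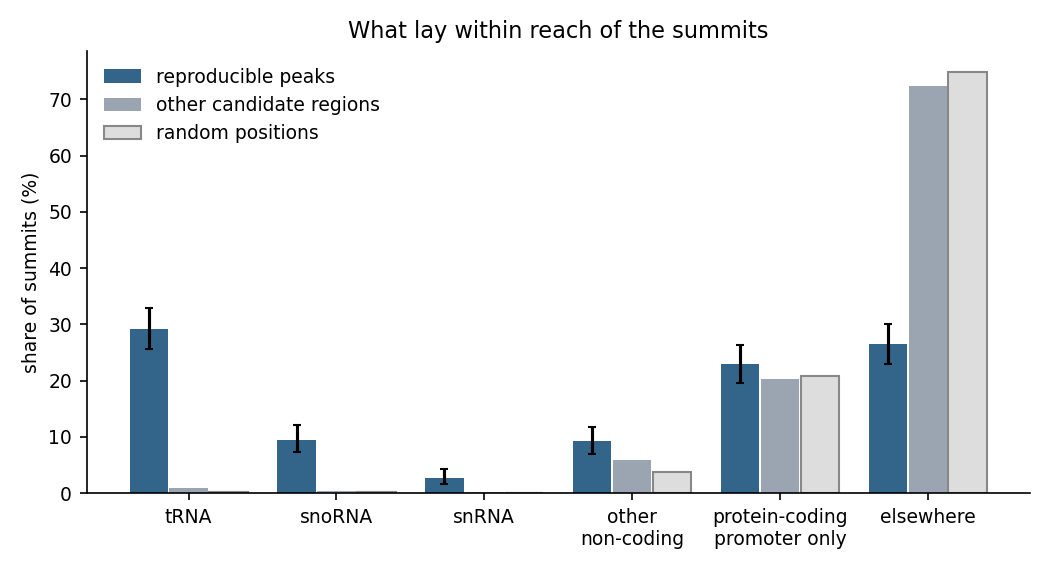
Share of summits (y axis, %) by what lay near them (x axis), for 620 nuclear reproducible peaks with 95% Clopper-Pearson intervals, 27673 other candidate regions and 19999 random positions. The other candidates are nuclear regions of the combined list that overlap no reproducible peak. Peaks near tRNA genes make up 29.2% of reproducible peaks and 0.986% of other candidates.

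Counted by gene, 206 of 612 nuclear tRNA genes had a reproducible summit within 200 bp (33.7%, interval 29.9 to 37.6), against 451 of 19973 protein-coding genes (2.26%). The same held for 59 of 346 snoRNA genes (17.1%), 17 snRNA genes (13.2% of them) and 236 of 7764 genes annotated as ncRNA (3.04%). Pseudogenes were below protein-coding genes, at 10 of 2128 (0.470%). Two-sided Fisher's exact tests against protein-coding genes, adjusted over 8 biotypes, gave adjusted p of 6.65e-159 for tRNA, 2.05e-31 for snoRNA, 1.68e-08 for snRNA, 3.97e-04 for ncRNA and 6.04e-10 for pseudogenes. These tests do not allow for gene length. Circular shifts of the summits, a setting added after seeing the data, keep gene lengths. They gave a mean of 27.9 bound ncRNA genes (adjusted permutation p = 0.0040) and 21.2 bound pseudogenes (adjusted permutation p = 0.0096). Most of the bound ncRNA genes shared their peaks with other small RNA genes: 157 of the 236 had summits only at peaks within 200 bp of a tRNA, snoRNA or snRNA gene. Among genes with no tRNA, snoRNA or snRNA gene within 400 bp, a setting added after seeing the data, 76 of 7245 ncRNA genes were bound (1.05%), against 1.40% of protein-coding genes, and no call was made (adjusted p = 0.0614 by Fisher's exact test). The ncRNA call ended without replicate 2 (2.60%, adjusted p = 0.397 by Fisher's exact test) and with summits up to 500 bp away (3.57%, adjusted p = 0.200 by the same exact test). The snRNA, snoRNA and ncRNA calls ended when the summit had to lie inside the gene body. No call was made for miRNA genes (3 of 261), lincRNA genes (3 of 194) or rRNA genes (0 of 20, which allows a share of up to 15%).

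The highest signals near tRNA genes were on X. A peak at 9743685 to 9743791 (signal 288), inside an intron of him-4, lay by the tRNA-Ala genes F15G9.t1 and F15G9.t2. Another at 3036042 to 3036207 (signal 282), outside protein-coding genes, lay by M02F4.t1 (tRNA-Gly) and M02F4.t2 (tRNA-Glu). The share of bound genes ran from 10% to 55.9% over 20 tRNA isotypes, and none passed the test against the other tRNA genes after adjustment, with 3 at an unadjusted p under 0.05 by Fisher's exact test. The summit of tRNA peaks had a median position 32.0 bp downstream of the 5' end of the nearest such gene.

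At snoRNA genes the median summit lay at -29.0 bp, where negative positions are upstream of the 5' end, and 47 of 59 summits (79.7%) were upstream (two-sided exact binomial p = 5.13e-06 against equal odds). The strongest were ZK994.7 on V, 8500410 to 8500681, in an intron of pxn-1 (signal 698, summit at -25 bp), C51F7.3 and C51F7.4 under 1 peak on V, 12303502 to 12303774, in an intron of frm-7 (signal 658), and W03C9.9 on II, 11960694 to 11960959 (signal 464, summit at -62 bp). Among snRNA genes the strongest were sls-2.4 on I (signal 294), sls-2.1 on II (signal 234), a gene under a peak on III, 10989555 to 10989717, in an intron of dhc-4 (signal 228), and sls-2.2 on II (signal 223). The sls-2 genes encode SL2 spliced leader RNAs, which are joined to the 5' ends of mRNAs by trans-splicing. Among ncRNA genes the strongest was rpr-1, the RNA of ribonuclease P, which cuts the 5' leader from tRNA precursors. Its peak on I, 13463830 to 13464113, had a signal of 471 and lay in an intron of ints-8.

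**Figure D3:**
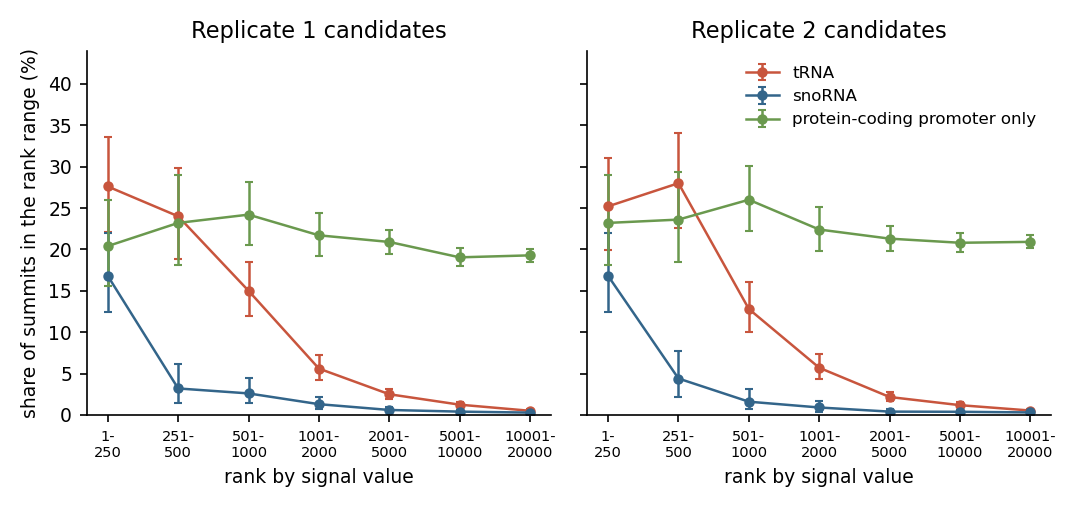
Share of summits (y axis, %, with 95% Clopper-Pearson intervals) near a tRNA gene, near a snoRNA gene or only in a protein-coding promoter, by rank range of signal value (x axis) in the candidate lists of replicate 1 (left) and replicate 2 (right). The tRNA share falls from 27.6% in ranks 1 to 250 to 0.50% in ranks 10001 to 20000 of replicate 1, and from 25.2% to 0.530% in replicate 2.

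Gene starts of all kinds held most of the summits. From 1000 bp upstream to 200 bp downstream of an annotated 5' end lay 465 of 620 summits (75%, interval 71.4 to 78.4), while the same windows cover 28.8% of the nuclear genome. The ratio was 2.60 (two-sided exact binomial p = 5.76e-125). Restricted to protein-coding genes, the share was 38.5% against 21.5% of the genome (exact binomial p = 4.83e-22). These tests and intervals treat peaks as the unit and cover sampling of peaks only. Promoter peaks had a median signal of 134.5 and the other 155 peaks one of 123.1, a difference of 11.4 (permutation p = 0.0075, two-sided, 100000 resamples). That call ended among the 310 strongest peaks, where the difference was 15.97 (permutation p = 0.0866).

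Protein-coding genes with a bound promoter numbered 291 of 19973 (1.46%). Of the 38 lists tested, cytosolic ribosomal protein genes had 15 of 81 bound (18.5%) against 1.39% of other genes (adjusted p = 2.58e-11 by Fisher's exact test). The strongest were rpl-3 on III, 3867444 to 3867710 (signal 718, summit at -279 bp), rpl-20 on IV, 4749967 to 4750188 (signal 426, summit at -301 bp), rpl-15 on IV, 654833 to 655030 (signal 371, summit at -341 bp), and rpl-35 on III, 7854583 to 7854797 (signal 352, summit at -450 bp). All 4 peaks lay outside protein-coding genes. The rpl-3 peak had the highest signal of any nuclear peak.

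Translation factor genes had 7 of 41 bound (17.1%, adjusted p = 3.62e-05 by Fisher's exact test), led by iff-2 (signal 187.8), eif-3.C (signal 162), eif-2Bgamma (signal 132) and eef-1G (signal 116.1). The eif-2Bgamma summit lay at -845 bp, within 200 bp of the snRNA gene sup-39. The eef-1G peak was weak in replicate 1 (signal 29.9, rank 4370), against rank 299 in replicate 2. The eif-2Bgamma peak ranked 500 in replicate 1 and 935 in replicate 2. With peaks near non-coding genes left out, a setting added after seeing the data, 4 translation factor genes stayed bound (9.76% against 0.873%, adjusted p = 0.0060 by Fisher's exact test). The call ended without replicate 2 (7.32% against 1.32%, adjusted p = 0.0823 by Fisher's exact test). Oxidative phosphorylation genes had 6 of 52 bound (11.5%, adjusted p = 8.01e-04 by Fisher's exact test), led by the cytochrome c oxidase genes cox-5A (signal 273), cox-6A (signal 215) and cox-5B (signal 171) and by nduf-2.2 (signal 129.3). The cox-6A summit, at -805 bp, lay by an snRNA gene, and the nduf-2.2 summit, at -816 bp, by the ncRNA gene T26A5.10 and nearer to dlc-1 (at -627 bp). The nduf-2.2 peak ranked 290 in replicate 1 and 2316 in replicate 2. Without peaks near non-coding genes, 4 members stayed bound (7.69% against 0.874%, adjusted p = 0.0090 by Fisher's exact test). This call ended among the 310 strongest peaks (5.77% against 0.793%, adjusted p = 0.0539 by Fisher's exact test). Chaperone genes had 7 of 67 bound (10.4%, adjusted p = 5.19e-04 by Fisher's exact test). They included hsp-60, a mitochondrial chaperonin (signal 251), dnj-13 (signal 238), cct-8 (signal 223) and dnj-19 (signal 144), and the last 3 of these peaks lay by ncRNA genes. The chaperone call ended when each summit was given only to its nearest 5' end (4.48% against 1.16%, adjusted p = 0.236 by Fisher's exact test). It also ended when peaks near non-coding genes were left out (4.48% against 0.879%, adjusted p = 0.134 by Fisher's exact test). Of the list of synMuv and chromatin genes, 8 of 110 were bound (7.27%, adjusted p = 0.0013 by Fisher's exact test), led by the histone acetyltransferase gene cbp-1 (signal 271), set-16 (signal 224), lin-54 (signal 202) and set-21 (signal 193). The last 3 of these peaks lay nearer to the 5' end of another gene. The set-16 peak was at -182 bp from set-16 and -164 bp from drr-2, the lin-54 peak at -360 bp from lin-54 and -33 bp from rpl-12, and the set-21 peak at -164 bp from set-21 and -90 bp from rpl-7A. Both rpl-12 and rpl-7A were among the bound ribosomal protein genes. The synMuv call ended with nearest 5' ends only (3.64% against 1.15%, adjusted p = 0.236 by Fisher's exact test).

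Chemoreceptor genes were bound less often than other genes, at 4 of 1285 (0.311%) against 1.54% (adjusted p = 5.19e-04 by Fisher's exact test). Among the 6067 genes with any candidate summit in the promoter, the chemoreceptor difference was no longer called (2.38% against 4.87%, adjusted p = 0.826 by Fisher's exact test), nor was it among the 310 strongest peaks (0.311% against 0.840%, adjusted p = 0.192 by Fisher's exact test). Among those 6067 genes ribosomal protein genes were at 26.3% against 4.59% (adjusted p = 1.54e-06 by Fisher's exact test) and translation factor genes at 28% against 4.70% (adjusted p = 0.0024 by Fisher's exact test). The chaperone, oxidative phosphorylation and synMuv lists also stayed past the threshold. None of the 6 lists of tissue markers passed. Germline markers had 3 bound (2.33%), intestine 2 of 150, neurons 1 of 132, hypodermis and seam 1 of 82, pharynx 1 of 120 and body wall muscle 0 of 47. The lowest adjusted p of the 6 was 0.848 by Fisher's exact test. With 1.46% of all protein-coding genes bound, few bound members are to be found in lists of 47 to 150 genes. A tissue preference is therefore not excluded.

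The other strongest peaks within 1000 bp of a protein-coding 5' end, by nearest gene, were at Y17G9B.5 (the peak also given for rpl-20), cdc-48.1, which encodes an AAA ATPase (II, signal 415), nspc-17 (X, signal 408) and tasp-1 (III, signal 387). Below them came sre-23, twk-5, Y75B12B.11, pdl-1, fbxb-58, egg-5, Y43F8C.7, F55A11.11 and epc-1, with signals from 342 for sre-23 to 280 for epc-1. The list closed with rps-1, Y22D7AL.10 (the peak also given for hsp-60), F44E5.4, wwp-1, wrt-3 and ZK1248.17, with signals from 264 for rps-1 to 234 for ZK1248.17. Of these genes, sre-23, twk-5, Y75B12B.11, pdl-1, Y43F8C.7, F55A11.11 and wrt-3 had a snoRNA gene within 200 bp of the same summit, and egg-5 and ZK1248.17 an snRNA gene.

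No reproducible summit lay within 1000 bp of Y5F2A.4 itself (IV, 11076085 to 11078582, minus strand) or of unc-119 (III, 10902641 to 10908935). The nearest reproducible summits were 49899 bp and 53593 bp away. At Y5F2A.4 neither replicate had a candidate summit within 1000 bp, and at unc-119 the strongest candidate in the combined list had a signal of 43.95.

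Chromosome X carried more summits than its length predicts. It held 143 of 620 (23.1%, interval 19.8 to 26.6) on 17.7% of the nuclear genome, a ratio of 1.31 (two-sided exact binomial p = 7.30e-04). In the 620 strongest regions of replicate 1 alone, without replicate 2, the ratio was 1.15 and the call ended (exact binomial p = 0.0918). Density was 8.07 peaks per Mb on X, 8.13 on III, 6.77 on I, 6.0 on IV, 5.69 on II and 3.39 on V. Of the X peaks, 85 were near a tRNA gene, and X carries 276 of the 612 nuclear tRNA genes. With peaks near tRNA genes left out, a setting added after seeing the data, the direction against length turned, to 58 of 439 summits on X (13.2%, interval 10.2 to 16.7, ratio 0.748, exact binomial p = 0.0145). X holds 13.7% of protein-coding genes and 15.1% of the other candidate regions, both inside that interval. The reversal was therefore seen against length only.

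**Figure D4:**
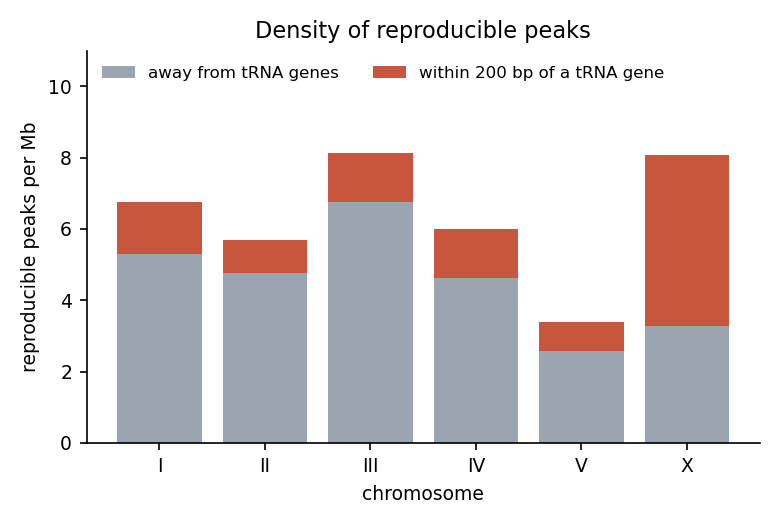
Reproducible peaks per Mb (y axis) on each nuclear chromosome (x axis), split into peaks within 200 bp of a tRNA gene and the rest. X has 8.07 peaks per Mb in all and 3.27 away from tRNA genes, while III has 8.13 and 6.75.

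Summits were rich in words of G and C and poor in runs of A and T. Of 2080 words of 6 bases, 454 were more frequent within 50 bp of summits than in equal windows 300 bp to each side, and 294 were less frequent. The enriched words with the lowest p were CGAACC, in 15.97% of 620 summit windows and 2.34% of 1240 flanking windows (adjusted p = 4.06e-23 by Fisher's exact test), GAACCC (13.5% against 2.02%) and ACCACT (15.8% against 3.06%). Among depleted words AAAAAT had the lowest p (20.3% against 45.6%). In the 181 tRNA peaks CGAACC reached 37.6% of windows. CGAACC and GAACCC read GGTTCG and GGGTTC on the other strand, the sequence of the B box, an internal promoter element of tRNA genes. With peaks near tRNA genes left out, CGAACC stayed enriched at 7.06% of windows (adjusted p = 0.0016 by Fisher's exact test). In the 381 autosomal peaks away from tRNA genes the enriched words with the lowest p were ACGCGC (11.3% against 1.18%) and GCGCGC (9.97% against 0.919%).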

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

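The tests in this part were chosen after the result was seen, except the share of unique 36-base words in tRNA windows. A bound on the ratio of bound shares, tRNA genes of unique sequence to those with identical copies, was also set in advance. No biological explanation that sets groups apart was tested, since the study has a single group.

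Peaks on the mitochondrial genome stood outside the nuclear comparisons and drew attention as a signal in data not otherwise reported on. There were 15 reproducible ones, with a median signal of 1056 against 131 for nuclear peaks, and they made up 9 of the 10 highest signals in the thresholded list. Mitochondrial candidate regions, whether or not they matched a reproducible peak, made up 9 of the 10 highest in the list of each replicate. The strongest reproducible peak, at 4459 to 5050, reached 4430 and lay in a coding exon. Of the 15 reproducible peaks, 11 had a candidate summit within 200 bp in both replicates. The next strongest, at 12298 to 12656 (signal 4211), had none in replicate 1. High copy number of mitochondrial DNA, not balanced by the control, is a candidate explanation. Its test asked whether candidate regions lay over the whole molecule. They covered 34.3% of it in each replicate, which neither meets nor rules out that explanation. Regions were at most 685 bp wide in replicate 1 and 435 bp in replicate 2. An even excess need not be called as adjoining regions, so the coverage cannot decide. The control reads were not analysed here.

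In the 181 summit windows at tRNA genes the median share of 36-base words found once in the genome was 62.1%, between the bounds set in advance for and against shared reads, and the true read length was not known. Genes with identical copies were bound more often than genes of unique sequence, at 38.4% against 18.2% (Fisher's exact p = 4.66e-06), so shared reads may add to the pattern. The ratio of the unique to the copied share was 0.474, short of the bound set in advance against shared reads. Reads shared between identical copies do not account for all of it. Of 121 tRNA genes with no identical copy and none with copies within 400 bp, 19.01% were bound, against 2.26% of protein-coding genes (Fisher's exact p = 8.64e-15). Genes with nearly identical copies, which can also share reads, were not left out of these 121. Of tRNA pseudogenes away from tRNA genes, 6 of 205 were bound (2.93%), less often than tRNA genes with and without copies together (Fisher's exact p = 5.80e-23). How much tRNA sequence these pseudogenes keep was not measured, so they cannot decide whether likeness of sequence alone is enough. General recovery of accessible sites, with no sequence of the tagged protein's own, stays open. CCTGCG was the single 6-base word enriched in tRNA, other X and other autosomal peaks, and it reached only 5.51% of windows where it was rarest. The 58 other X peaks gave only 14 enriched words, against 273 for tRNA and 272 for other autosomal peaks. That small set limits how many words could be shared. No library from worms without the tag was analysed here.

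The excess on chromosome X is consistent with the concentration of tRNA genes there. Without peaks near tRNA genes the ratio to X's share of the genome was 0.748, below 1. That fall was partly by construction, since 85 of the 181 peaks left out were on X. X's share of the other candidate regions, 15.1%, was also below its 17.7% of the nuclear genome. A ratio below 1 therefore cannot by itself decide on this explanation. Stronger binding of X-linked than autosomal tRNA genes could not be told apart from equal binding, with 35.1% and 32.4% bound and an odds ratio of 1.13 (Fisher's exact p = 0.493).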

How the results depend on the processing

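The promoter share, the overlap of replicates, the number of lists called and the number of enriched 6-base words kept their direction and their side of the threshold, or stayed within 1.5 times, under every alternative tried. In all, 46 of 51 recomputed summary values did so, counting the 334 enriched of 32896 8-base words, a number that cannot be compared with 454 of 2080. The promoter share ran from 66.1% to 72.1% with 1 replicate left out. The number of lists called was 8 without replicate 1 and 7 without replicate 2, and ran from 4 to 9 over all alternatives. The lists called were not always the same: with the stronger peaks 5 were called, of which 4 were among the 6 of the main setting. Taking the stronger peaks only left 317 reproducible peaks, by construction, and ended the call on promoter signal (difference 15.97, permutation p = 0.0866). Requiring the summit inside the gene body left 2 biotypes called, tRNA and pseudogene. The X ratio ran from 1.15 to 1.27 with 1 replicate left out, and the call ended without replicate 2. Against X's share of genome length it reversed to 0.748 when peaks near tRNA genes were left out. The direction of the ncRNA result turned, to 1.02% against 1.49% of protein-coding genes (adjusted p = 0.0053 by Fisher's exact test), when peaks near tRNA, snoRNA or snRNA genes were left out, partly by construction, since genes beside those peaks could no longer be bound. With such genes left out instead it was 1.05% against 1.40%, with no call (adjusted p = 0.0614 by the same exact test). These 3 settings were chosen after seeing the data. Neither ncRNA comparison allows for gene length, so its direction against protein-coding genes cannot be read as avoidance of ncRNA genes. Against circular shifts, which keep gene lengths but used all peaks, 236 ncRNA genes were bound and the shift mean was 27.9. Of 90 recomputed values for single lists, biotypes and words, 76 kept their call, 12 no longer passed and 2 turned direction. Apart from the counts set by construction, the cause was not tested. Read depth is unknown, so it cannot be said which weak sites were missed.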

Other observations

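The test in this part was chosen after the result was seen. Away from tRNA genes, 4 of the 5 strongest X peaks lay outside the promoters of protein-coding genes. The peak at 11094078 to 11094334 (signal 506) lay outside protein-coding genes, as did those at 16682003 to 16682228 (signal 405) and 4209155 to 4209390 (signal 402), and the one at 6296423 to 6296717 (signal 398) lay in an intron of mom-1. The other, at 14525774 to 14526029 (signal 408), lay at -734 bp from nspc-17. Among the 58 X peaks away from tRNA genes, CCTGCG was in 27.6% of summit windows and 1.72% of flanking windows (adjusted p = 4.31e-04 by Fisher's exact test).

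The longer word CTGCGCGA, which reads TCGCGCAG on the other strand, was in 11 of those 58 X windows (18.97%) and in 0 of 381 autosomal windows away from tRNA genes, which allows a share of up to 0.787% (Fisher's exact p = 8.84e-11). It was picked because it stood out on X, so this p is too small. No 8-base word passed adjustment against flanks in the X peaks taken alone. The word occurs 7.84 times per Mb on X and 4.72 times per Mb on autosomes. X peaks with the word had a median signal of 348, and those without it 130, and 6 of the 12 strongest held it. As background, TCGCGCAG is part of the MEX motif found at recruitment sites of the dosage compensation complex on X. Whether these peaks are such sites was not tested, since no map of them was used here.

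Of snoRNA genes, 25 of 183 inside a protein-coding gene on the same strand were bound (13.7%), and 34 of 163 others (20.9%, Fisher's exact p = 0.0863).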
